A study of Mus musculus with 6 samples.

How the data were processed

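RNA was measured in 6 libraries of 1 wild-type macrophage line, 3 labelled mock and 3 labelled as infected with Candida albicans, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, enriched for polyA and sequenced as 150 bp paired-end reads on an Illumina NovaSeq. The submitters' processing notes name FastQC, cutadapt, Salmon, DESeq2 and the mouse build GRCm38, without versions. The deposited tables hold, per the file headers, an estimated count, an effective length and a TPM for each transcript, under the column names that kallisto writes, so which quantifier made the values is not settled here. The authors' estimated counts need not be whole, since reads shared by similar transcripts are divided among them. The deposited TPM values, which are scaled to the same sum in each library, were used only for an alternative of the composition shares, and the deposited effective lengths only for an alternative fit.

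Each table listed 130329 transcripts. They were joined to gene symbols through a RefSeq gene table of assembly GRCm38.p6, ignoring the version number of the accession. This matched 106810 transcripts (82.0%, and 54.5% with the version as well), holding 95.4 to 95.9% of counts per library. The other 23519, of which 23445 were predicted models, were kept as single features and are not named. Counts of a gene with both matched and unmatched transcripts can shift with how reads were divided between them. As the transcript set did not match the release of the table, no genome coordinates are given. The tables held 0 transcripts of the mitochondrial chromosome, so the planned mitochondrial share and the fit without mitochondrial genes were not run, and as RefSeq has no class of retained introns the share of non-coding transcripts of protein-coding genes was used. Paralogs and pseudogenes can share reads, which the quantifier divides by its own model, and strand use is not given in the sources used here.

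Counts were summed per gene, rounded to whole numbers, filtered with filterByExpr and scaled with TMM (factors 0.973 to 1.03). The test was edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3 with group as the term, two-sided, with Benjamini-Hochberg adjustment over 17274 features (12982 genes and 4292 unmatched transcripts) and a threshold of 0.05. A SE is the absolute log2 fold change divided by the root of its F statistic. The fitted common biological coefficient of variation was 0.479. CPM values (counts per 1000000 of the scaled library total) are scaled by TMM except those of untested markers, and log2 CPM used a prior count of 2. A depth of 15117813 to 22410560 counts per library bounds counting error only. Gene lists (28, of which 21 were pathways and 7 markers of other cells, with 785 entries, 5 of them unmatched) and the planned tests were fixed before the data were examined. Lists with 5 or more tested members (22) went through camera (limma 3.58.1) with a correlation preset to 0.01, and also with an estimated correlation and through fry. fry tests whether a list's genes move one way and compares no list with other genes. The spread of a list was its median SD of log2 CPM over the 6 libraries, set against 10000 random lists of the same size drawn from 20 bins of mean expression.

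The rule for named genes was fixed before the data were examined. It took the 8 called genes with the largest rise and the 8 with the largest fall, of which there were none. For each list it took called members or, with none called, the 2 most abundant tested members, and for each group its 3 most abundant genes. After the data were seen, the 3 members of each pathway list with the largest SD over the libraries (mean of 5 CPM or more) and the 25 genes with the largest SD overall (mean of 20 CPM or more) were added, and some of these are named in the text, as are members of counts of 5 or fewer in the fit without the libraries labelled mock 2 and Ca 2. Some genes that these rules take are not reported here.

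Alternatives were DESeq2 size factors in the edgeR fit, library size only, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0 (Wald test, 57 features with no p, as its check on outlying counts by Cook's distance removed them, 13 of them list members), limma-voom, an effective-length offset, protein-coding genes only, a threshold on fold change of 1.5 (glmTreat), a replicate block, and leaving out each library in turn. Leaving out unmatched transcripts and leaving out the libraries labelled mock 2 and Ca 2 were added after the data were seen. So were DESeq2 runs over the 10 splits of the libraries and without unmatched transcripts, and a correlation check with each library thinned to the shallowest depth in 10 draws. A direction was compared between settings only where at least 1 of them made a call. The edgeR test was tested on simulated counts of the Ca against mock comparison, with 17274 features of which 200, drawn at random, were changed. With the spread fitted to these libraries it called 28% of genes changed by 2-fold, 56% at 4-fold, 72% at 8-fold and 72% at 16-fold, and 4 unchanged genes. With a dispersion of 0.01 it called 88% at 2-fold and 100% at 4, 8 and 16-fold, and 11 unchanged genes. Shares were compared with exact two-sided permutation tests, and Python with matplotlib drew the figures.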

Results

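Polyadenylated RNA was sequenced from immortalized bone marrow-derived macrophages, a mouse cell line grown from marrow precursors and kept in medium conditioned by L929 cells. The 6 libraries carried 3 mock labels and 3 labels of infection with the yeast Candida albicans for 4 h at a multiplicity of infection of 1. The comparison asks which host genes differ in expression during infection. Total estimated counts were 15117813, 18226129 and 20346574 in the libraries labelled mock 1, mock 2 and mock 3, and 22410560, 18747645 and 20465117 in those labelled Ca 1, Ca 2 and Ca 3. The labels did not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Means are given ± SD over n = 3 libraries, fold changes as the log2 of Ca over mock ± SE, and libraries are named by their deposited label throughout.

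Inflammatory genes were abundant in 3 libraries, and these did not follow the labels. Tnf, the gene for tumour necrosis factor, stood at 155 CPM (counts per 1000000) in Ca 1, 153 CPM in Ca 3 and 155 CPM in the library labelled mock 2. In the library labelled Ca 2 it stood at 13.0 CPM, beside 11.1 CPM in mock 1 and 10.5 CPM in mock 3. The group means of Tnf were therefore 59.0 ± 83.4 CPM for mock and 107 ± 81.4 CPM for Ca, a log2 fold change of 0.86 ± 1.32 (edgeR adjusted p = 0.999). Acod1, which makes the antimicrobial metabolite itaconate, the chemokine gene Cxcl2 and the glucose transporter gene Slc2a1 separated the libraries in the same way. Of these, Acod1 and Cxcl2 were chosen by their spread, after their values were seen. Lyz2 (lysozyme) and Csf1r, the receptor for the growth factor of macrophages, had log2 fold changes of -0.02 ± 0.08 and 0.05 ± 0.05.

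**Figure D1:**
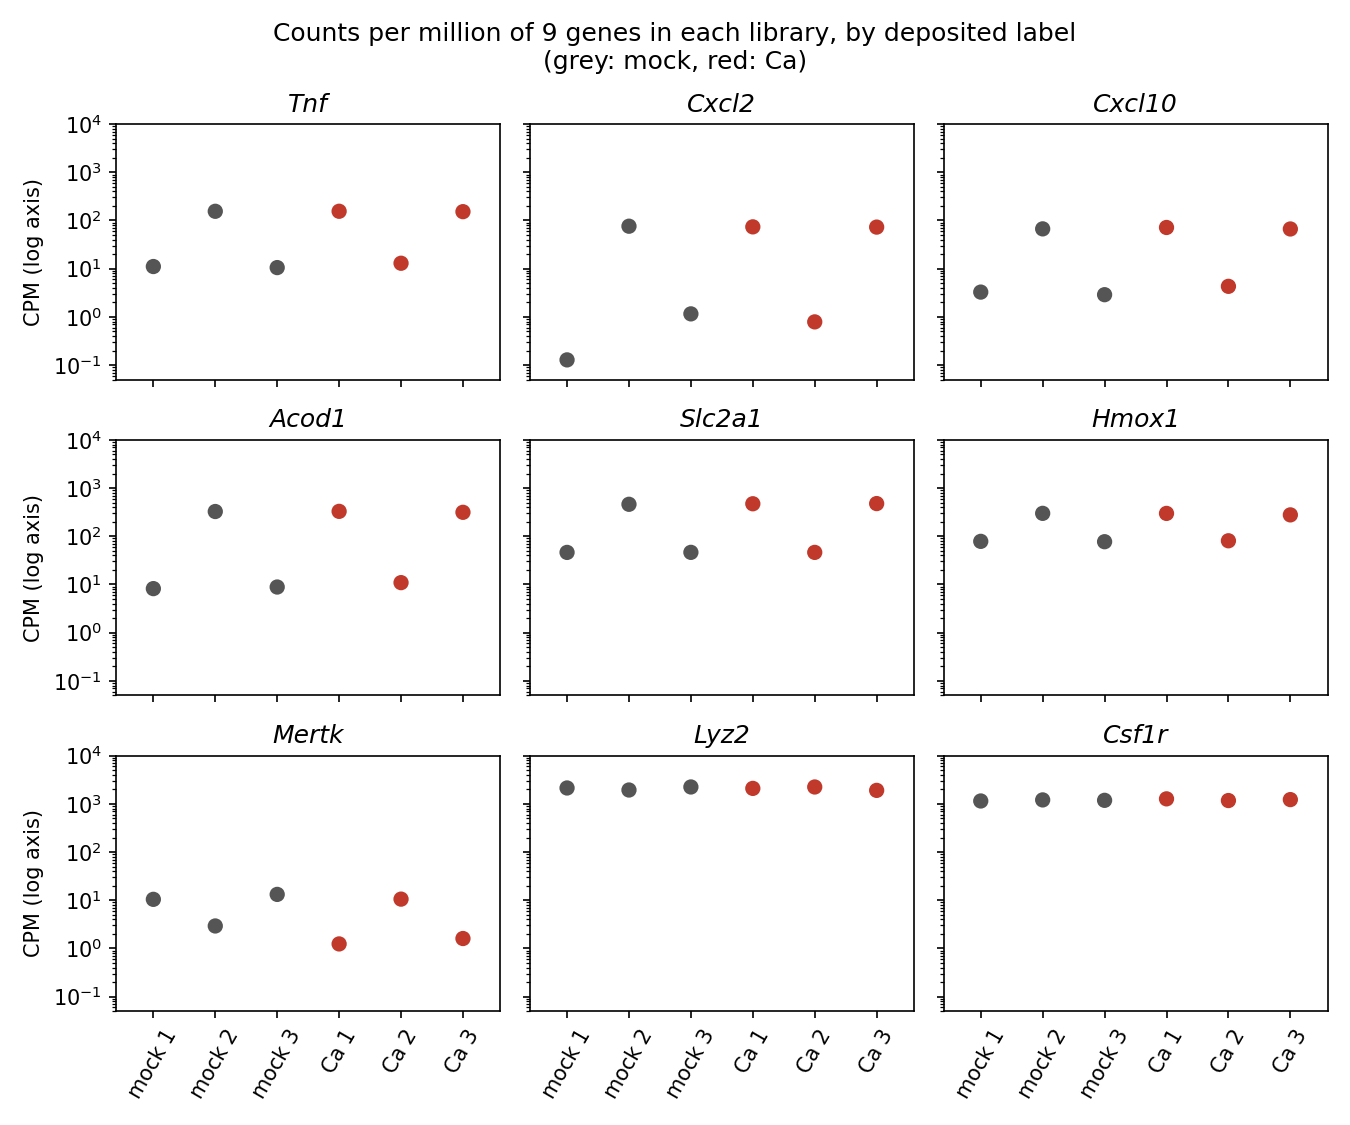
CPM on a log axis for 9 genes, with 1 point per library, grey for the mock label and red for the Ca label. Tnf lay at 155 CPM in mock 2 and at 13.0 CPM in Ca 2, and Lyz2 lay between 1905 and 2242 CPM in the 6 libraries. Cxcl2, Cxcl10, Acod1, Hmox1 and Mertk were chosen by their spread, after their values were seen.

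Between the labelled groups, 0 of 17274 features were called higher and 0 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 306 features, 140 higher and 166 lower, which is 1.77% of those tested, and the smallest adjusted p was 0.314. The 3 values of each group did not overlap for 1174 features (6.80%), where chance gives 10%. The limma-voom fit also called 0, and DESeq2 called 35 higher and 37 lower. Of these calls 69 were single transcripts absent from the gene table, and 58 had an estimated count that rounded to 0 in at least 1 library. The 3 named genes among DESeq2's calls, given here after their values were seen, were Tmem245, a membrane protein gene, and the ubiquitin ligase genes Rnf111 and Rnf216. Tmem245 stood at 12.9 ± 2.74 CPM in mock and 42.8 ± 1.97 CPM in Ca, with a DESeq2 log2 fold change of 1.73 ± 0.20 (adjusted p = 3.78e-14) and an edgeR adjusted p of 0.314. Rnf111 had a DESeq2 log2 fold change of 0.41 ± 0.11 (adjusted p = 0.0316, edgeR adjusted p = 0.864) and Rnf216 of -0.29 ± 0.08 (adjusted p = 0.0248, edgeR adjusted p = 0.999). With the single transcripts left out, a step added after the data were seen, DESeq2 called Tmem245 but neither of these 2, whose log2 fold changes were then 0.40 ± 0.11 and -0.30 ± 0.09 (adjusted p = 0.999 for both).

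Of 667 tested members of the gene lists fixed before the data were examined, 0 were called by edgeR and 0 by limma-voom, and 0 by edgeR when adjusted over the list alone. DESeq2 called 0 of the 654 members to which it gave a p-value, and gave none to 13, among them Tnf, Cxcl2, Cxcl10, Acod1, Slc2a1, Egr1 and Saa3, so its count says nothing about these. The 2 members with an unadjusted edgeR p under 0.05 were Blvrb, a biliverdin reductase gene, with a log2 fold change of 0.17 ± 0.07, and the mitotic phosphatase gene Cdc25c, with 0.50 ± 0.18. As whole lists, 8 of 22 passed camera's test with a preset correlation as higher in Ca and 0 as lower. These were NF-kB targets, cholesterol biosynthesis, the type I interferon response, glycolysis, hypoxia targets, chemokines, immediate early genes and antimicrobial effectors. None of the 8 passed when the correlation among members was estimated (adjusted p = 0.801 with an estimated correlation, for each of the 8) or by fry (adjusted p = 0.760). The estimates for the 8 ran from 0.184 (antimicrobial effectors) to 0.93 (NF-kB targets), far from the preset of 0.01. They come from residuals around the labelled group means, so mock 2 and Ca 2, which lay with the other group, add to them. Without mock 1, mock 3, Ca 1 or Ca 3 the number of lists passing was 0, without the library labelled mock 2 it was 13 higher, and without the library labelled Ca 2 it was 12 higher and 1 lower.

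**Figure D2:**
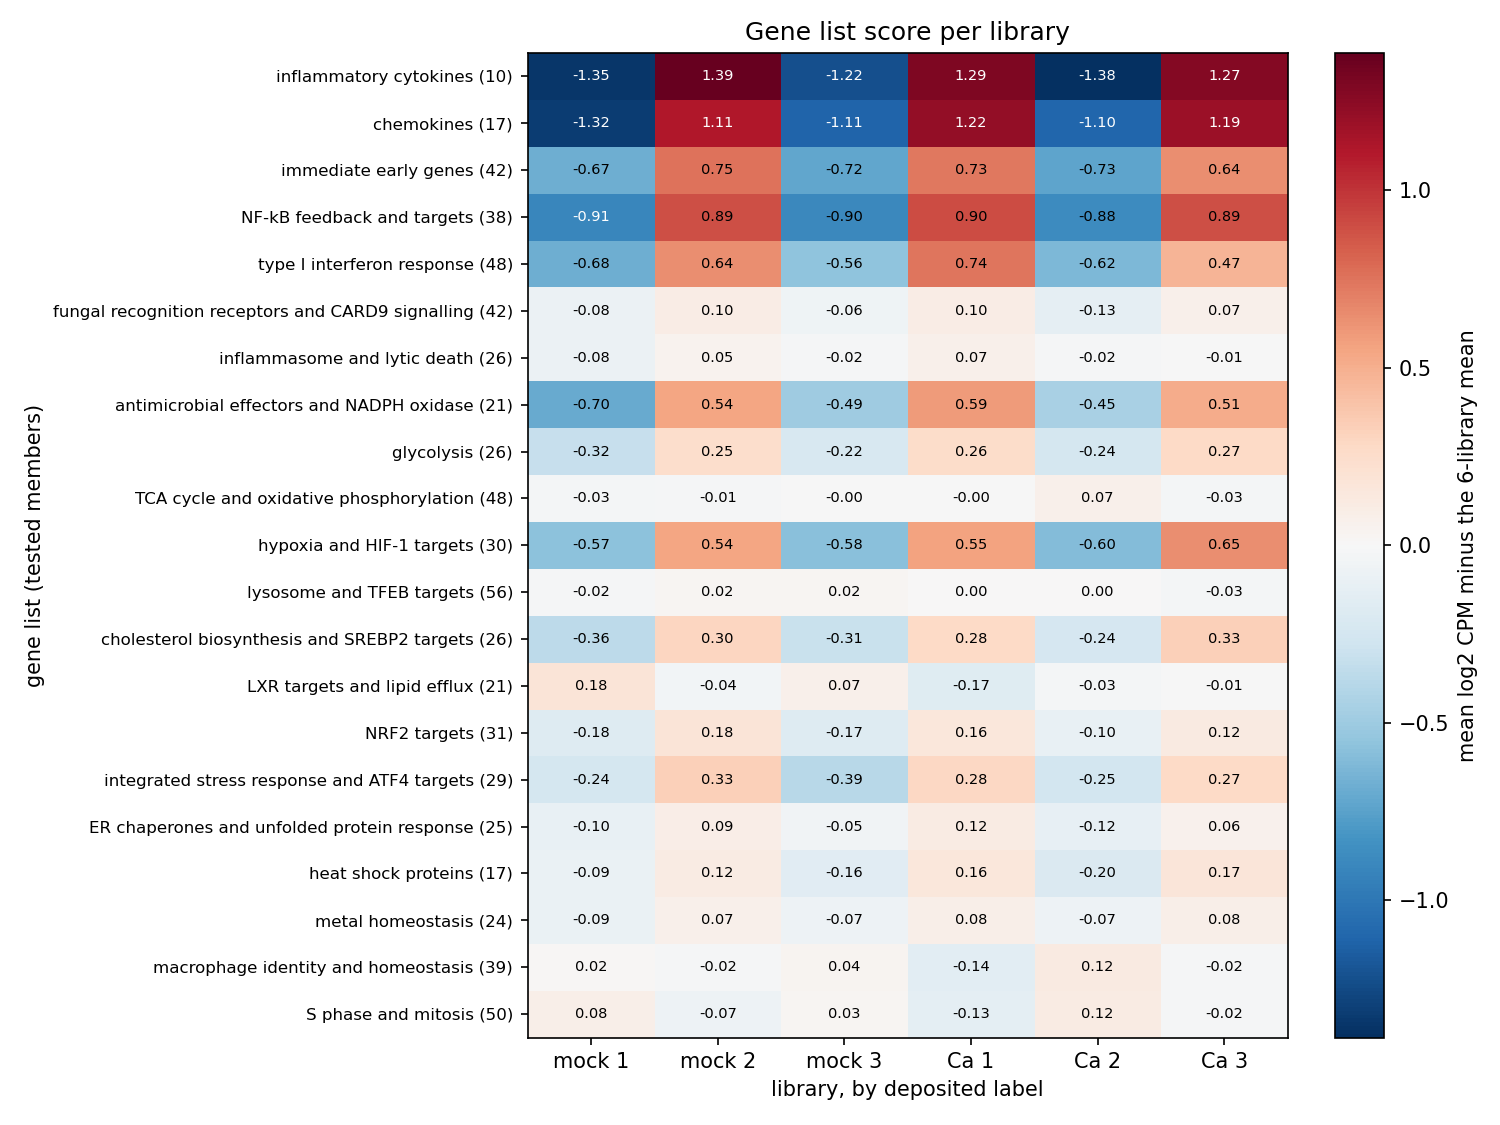
Score of each of 21 gene lists in each library, as the mean over tested members of log2 CPM minus the mean of the 6 libraries, with the number of tested members in brackets. The NF-kB score was 0.89 in mock 2, 0.90 in Ca 1 and 0.89 in Ca 3, against -0.91, -0.90 and -0.88 in mock 1, mock 3 and Ca 2.

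Cytokine and chemokine genes had the widest spread among libraries of the lists tested. Of 10 tested cytokine genes 9 had a positive log2 fold change and 0 passed the test (median 0.74, camera adjusted p = 0.0671). Il1rn, which encodes an antagonist of the interleukin 1 receptor, was the most abundant at 85.3 ± 97.7 CPM in mock and 144 ± 97.7 CPM in Ca, a log2 fold change of 0.76 ± 1.01. Csf1, among the members with the largest spread and so chosen after its values were seen, stood at 12.2, 108 and 16.6 CPM in mock 1 to 3 and at 111, 13.9 and 108 CPM in Ca 1 to 3. Of 17 chemokine genes 14 had a positive log2 fold change and 0 passed (median 0.69, camera adjusted p = 0.00449, and adjusted p = 0.801 with an estimated correlation). The most abundant, Ccl9, had a log2 fold change of 0.38 ± 0.53, and Cxcl14 had -0.08 ± 0.06. Cxcl2, which attracts neutrophils, stood at 76.1 CPM in mock 2 and 0.788 CPM in Ca 2, and the interferon-induced Cxcl10 at 67.0 CPM in mock 2 and 4.31 CPM in Ca 2, both also chosen by their spread. The median SD of log2 CPM over the 6 libraries, taken without regard to labels, was 1.56 for cytokines and 1.27 for chemokines, where 10000 random lists of like abundance had medians of 0.308 and 0.294 and all lay below the observed value.

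Immediate early genes and NF-kB targets, which respond within hours to receptor signalling, were placed the same way. Of 42 immediate early genes 34 had a positive log2 fold change and 0 passed (median 0.43, camera adjusted p = 0.00449, and adjusted p = 0.801 with an estimated correlation). Junb and Atf3, which encode transcription factors, had log2 fold changes of 0.34 ± 0.47 and 0.50 ± 0.65. Egr1 and Egr2, chosen by their spread, stood at 93.3 and 37.3 CPM in mock 2 and at 8.46 and 3.52 CPM in Ca 2. Among 38 NF-kB targets 36 had a positive log2 fold change and 0 passed (median 0.46, camera adjusted p = 2.45e-05, and adjusted p = 0.801 with an estimated correlation). Tnfaip2 had a mean of 423 ± 312 CPM in mock and 597 ± 307 CPM in Ca (0.50 ± 0.64), and the adhesion receptor gene Cd44 had a log2 fold change of 0.18 ± 0.27. Traf1, an adaptor of tumour necrosis factor receptors chosen by its spread, stood at 0.321, 35.3 and 1.11 CPM in mock 1 to 3 and at 39.9, 0.893 and 36.1 CPM in Ca 1 to 3. Ptgs2, the inducible cyclooxygenase, also chosen by its spread, stood at 29.5 CPM in mock 2 and 1.58 CPM in Ca 2.

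Type I interferon response genes gave 43 of 48 positive log2 fold changes and 0 calls (median 0.28, camera adjusted p = 0.000217, and adjusted p = 0.801 with an estimated correlation). Parp14 had a log2 fold change of 0.24 ± 0.53 and the double-stranded RNA sensor gene Oas3 of 0.07 ± 0.12. Rsad2, which encodes the antiviral protein viperin and was chosen by its spread, stood at 3.33, 29.5 and 5.34 CPM in mock 1 to 3 and at 26.3, 5.46 and 22.7 CPM in Ca 1 to 3. Gbp2, a guanylate-binding protein gene also chosen by its spread, stood at 23.4 CPM in mock 2 and 2.99 CPM in Ca 2.

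Receptors and adaptors for fungal recognition went both ways, with 21 of 42 positive log2 fold changes and 0 calls (camera adjusted p = 0.850). The list's median (0.00) and mean (0.02) were slightly positive while camera ranked it lower. Lgals3, a galectin gene, had a log2 fold change of 0.04 ± 0.05 and the scavenger receptor gene Cd36 of -0.10 ± 0.06. Clec4e, which encodes the C-type lectin Mincle and was chosen by its spread, stood at 377 CPM in mock 2 and 48.6 CPM in Ca 2. Tlr2, also chosen by its spread, stood at 565 and 168 CPM. Inflammasome and lytic death genes had 14 of 26 positive log2 fold changes and 0 calls (camera adjusted p = 0.859), again with a positive median (0.01) and a lower rank. Txnip, a thioredoxin-binding protein gene, stood at 265 ± 85.9 CPM in mock and 194 ± 70.9 CPM in Ca (-0.45 ± 0.35), and Nek7, a kinase gene needed for NLRP3 activation, at -0.08 ± 0.12 on the log2 scale. Nlrp3 itself, chosen by its spread, stood at 156 CPM in mock 2 and 68.8 CPM in Ca 2. Of 21 antimicrobial effector genes 16 had a positive log2 fold change and 0 passed (median 0.22, camera adjusted p = 0.0162, and adjusted p = 0.801 with an estimated correlation). Cybb, the catalytic subunit of the NADPH oxidase, had a log2 fold change of 0.34 ± 0.39, and Saa3, a serum amyloid gene chosen by its spread, stood at 23.1 CPM in mock 2 and 0.945 CPM in Ca 2.

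Among metabolic lists, glycolysis had 20 of 26 positive log2 fold changes and 0 calls (median 0.17, camera adjusted p = 0.0028, and adjusted p = 0.801 with an estimated correlation). Gapdh stood at 4170.0 ± 393 CPM in mock and 4637 ± 315 CPM in Ca (0.15 ± 0.08), and Eno1 had a log2 fold change of 0.17 ± 0.08. Slc2a1 stood at 46.3, 461 and 46.4 CPM in mock 1 to 3 and at 473, 46.3 and 477 CPM in Ca 1 to 3, a log2 fold change of 0.85 ± 1.21. Hk2, a hexokinase gene chosen by its spread, stood at 219 CPM in mock 2 and 72.3 CPM in Ca 2. Hypoxia targets, which as written share Slc2a1, Hk2, Pfkfb3 and Pfkfb4 with that list, had 24 of 30 positive log2 fold changes and 0 calls. Their median was 0.30 (camera adjusted p = 0.0028, and adjusted p = 0.801 with an estimated correlation). The lipid droplet gene Plin2 had a log2 fold change of -0.07 ± 0.13. The TCA cycle and oxidative phosphorylation list had 38 of 48 positive log2 fold changes and 0 calls (median 0.03, camera adjusted p = 0.205). Its members were the steadiest among libraries of the 22 lists, with a median SD of 0.072 on the log2 scale, below all 10000 random lists (median 0.113). Atp5b and Atp5a1, subunits of ATP synthase, had log2 fold changes of 0.03 ± 0.04 and 0.04 ± 0.05.

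Cholesterol biosynthesis genes had 23 of 26 positive log2 fold changes and 0 calls (median 0.27, camera adjusted p = 9.79e-05, and adjusted p = 0.801 with an estimated correlation). Srebf2, the transcription factor gene of the pathway, had a log2 fold change of 0.20 ± 0.20. LXR targets had 10 of 21 positive log2 fold changes and 0 calls (median -0.01, camera adjusted p = 0.891). The desaturase gene Scd2 had 0.32 ± 0.24, while the sterol exporter gene Abcg1, chosen by its spread, stood at 111 CPM in mock 2 and 235 CPM in Ca 2. Lysosome genes had 17 of 56 positive log2 fold changes and 0 calls (median -0.03, camera adjusted p = 0.461), and the cathepsin genes Ctsb and Ctsd had -0.02 ± 0.04 and -0.08 ± 0.10.

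None of the 5 stress-related and metal lists passed camera, and 0 of their members were called by edgeR. NRF2 targets had 23 of 31 positive log2 fold changes (median 0.05, camera adjusted p = 0.108), with 0.01 ± 0.06 for Ftl1 and 0.08 ± 0.06 for Fth1, the ferritin genes, which also belonged to the metal homeostasis list (17 of 24 positive, median 0.04, camera adjusted p = 0.365). Hmox1, which encodes heme oxygenase and was chosen by its spread, stood at 78.5, 299 and 77.2 CPM in mock 1 to 3 and at 298, 80.7 and 278 CPM in Ca 1 to 3. ATF4 targets had 23 of 29 positive log2 fold changes (median 0.06, camera adjusted p = 0.114), with 0.06 ± 0.05 for Shmt2 and 0.04 ± 0.07 for Phgdh, enzymes of serine metabolism. For ER chaperones the count was 17 of 25 (median 0.04, camera adjusted p = 0.299), with 0.06 ± 0.09 for Calr and 0.17 ± 0.24 for Hspa5. Heat shock protein genes had 16 of 17 positive (median 0.10, camera adjusted p = 0.0963), with 0.07 ± 0.03 for Hsp90ab1 and 0.12 ± 0.09 for Hspa8.

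Macrophage identity genes had 18 of 39 positive log2 fold changes and 0 calls (median -0.03, camera adjusted p = 0.702). Mertk, a receptor for the uptake of dying cells chosen by its spread, stood at 10.4, 2.93 and 13.2 CPM in mock 1 to 3 and at 1.24, 10.6 and 1.61 CPM in Ca 1 to 3. The transcription factor gene Maf, also chosen by its spread, stood at 4.28 CPM in mock 2 and 30.4 CPM in Ca 2. Cell cycle genes had 21 of 50 positive log2 fold changes and 0 calls (median -0.02, camera adjusted p = 0.850), with -0.04 ± 0.09 for Mki67 and 0.03 ± 0.05 for Top2a, both markers of dividing cells. The most abundant genes of both groups were Ftl1, the elongation factor gene Eef1a1 and Fth1. Eef1a1 stood at 9872 ± 205 CPM in mock and 9929 ± 238 CPM in Ca.

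Markers of other cell types were mostly near or below the filter on low counts. For fibroblasts and erythroid cells 0 markers were tested, with Col1a1 at no more than 0.293 CPM and Hba-a1 at no more than 0.244 CPM in any library. Of the T cell markers 5 were tested (camera adjusted p = 0.461), the highest being Cd28 at 54.9 ± 6.14 CPM in mock and 49.7 ± 1.37 CPM in Ca, followed by Lck at 1.31 ± 0.28 and 1.11 ± 0.48 CPM. The B cell marker Cd22 had means of 0.653 and 0.794 CPM. The neutrophil markers Mmp8 and Csf3r had log2 fold changes of -0.01 ± 0.24 and -0.72 ± 0.51, and S100a8 reached 0.914 CPM. For endothelium, Vwf had 79.7 ± 8.84 CPM in mock and 70.0 ± 6.35 CPM in Ca and Egfl7 had a log2 fold change of -0.14 ± 0.14. The dendritic cell markers Xcr1 and Batf3 had means of 1.07 and 1.28 CPM in mock. None of the 17 tested markers was called by edgeR, DESeq2 or limma-voom.

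The whole profiles placed the libraries as Tnf did. Across 9288 genes with a mean of 10 CPM or more, which are not independent replicates, the library labelled mock 2 correlated at r = 0.980 with both Ca 1 and Ca 3 and at no more than 0.928 with a mock library. The library labelled Ca 2 correlated at 0.968 with mock 3 and 0.957 with mock 1, and at no more than 0.921 with a Ca library. Genes differing by 2-fold or more numbered 500 between mock 1 and mock 2, and 122 between mock 1 and Ca 2. The first principal component held 61.9% of the variance, with mock 2 at 26.1, Ca 1 at 25.8 and Ca 3 at 24.8, and mock 1, mock 3 and Ca 2 at -27.8, -23.0 and -25.9. No pair of libraries matched within sampling noise, as chi-square per gene was 6.83 or more where counting error gives about 1, so no 2 were merged as repeats of 1 library. Libraries made from 1 culture would also exceed 1, so this does not show separate cultures.

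**Figure D3:**
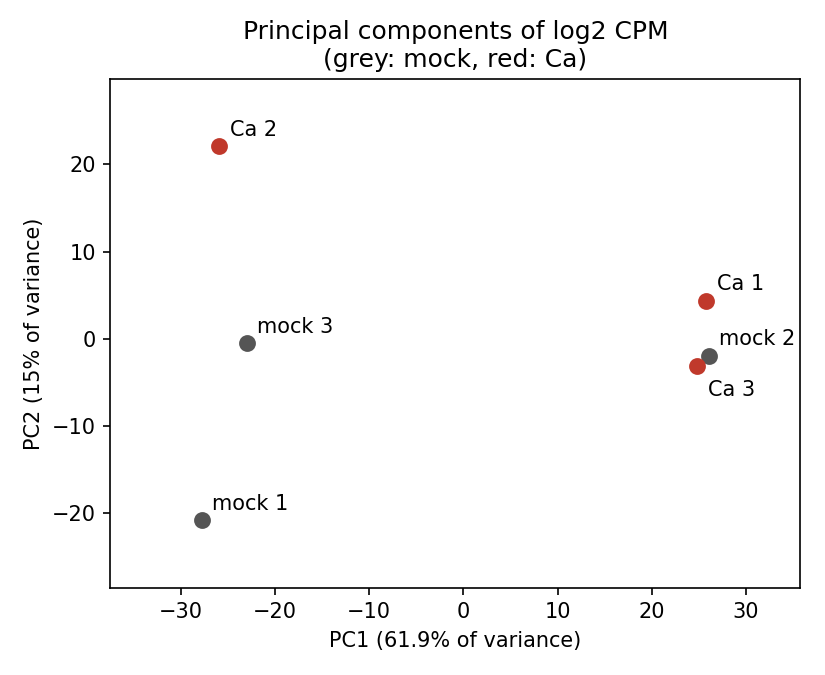
Libraries on the first and second principal components of log2 CPM of 9288 genes, with 1 point per library, grey for the mock label and red for the Ca label. On the first axis, with 61.9% of the variance, mock 2 lay at 26.1 and Ca 2 at -25.9.

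Because these libraries stood apart from their groups, each count was also made without the libraries labelled mock 2 and Ca 2, a choice made after the data were seen. That left 2 libraries per group. Among 18030 features, 1396 were then higher and 788 lower in Ca, 428 and 196 of them by 2-fold or more, by the same edgeR test. The libraries were left out for the outcome tested, so these p-values are not independent evidence of an infection response. Calls higher and lower were 8 and 0 of 10 cytokines, 12 and 0 of 17 chemokines, 28 and 2 of 42 immediate early genes, 29 and 0 of 38 NF-kB targets, and 20 and 0 of 48 interferon response genes. They were 12 and 9 of 42 fungal recognition genes, 4 and 5 of 26 inflammasome genes, 10 and 1 of 21 antimicrobial effectors, 17 and 0 of 26 glycolysis genes, 17 and 0 of 30 hypoxia targets, and 18 and 0 of 26 cholesterol biosynthesis genes. For the TCA cycle and oxidative phosphorylation 1 and 0 of 48 were called, for lysosome genes 5 and 5 of 56, for LXR targets 2 and 5 of 21, for macrophage identity 4 and 12 of 39, and for the cell cycle 1 and 7 of 50. NRF2 targets had 9 and 3 of 31, ATF4 targets 10 and 1 of 30, ER chaperones 5 and 0 of 25, heat shock proteins 5 and 0 of 17, and metal homeostasis 7 and 1 of 24. Among markers of other cells, 1 endothelial marker, Vwf, was lower. The counts of 5 or fewer included, among those higher, Nlrp3, Casp4, Ninj1 and Cflar of the inflammasome list, Cycs of the TCA cycle list, Ctsz, Atp6v1h, Sqstm1, Tfe3 and Rragc of the lysosome list, Scd2 and Fasn of the LXR list, Cx3cr1, Spi1, Cebpb and Cd74 of macrophage identity, Cdk1 of the cell cycle, Hspa5, Dnajb11, Hyou1, Edem1 and Herpud1 of the ER chaperones, and Hspa8, Hspa4, Hsph1, Hsp90aa1 and Chordc1 of the heat shock proteins. Among those lower they included the immediate early genes Dusp6 and Klf4, Txnip, P2rx7, Ripk1 and Naip5 of the inflammasome list, the antimicrobial gene Mpeg1, Ctsd, Lipa, Scarb2, Gpnmb and Tfeb of the lysosome list, Abcg1, Apoe, Smpdl3a, Pltp and Pparg of the LXR list, the NRF2 targets Osgin1, Mgst1 and Trim16, the ATF4 target Sesn2 and the iron exporter gene Slc40a1. By camera 15 lists passed as higher and 2 as lower, and with an estimated correlation 2 passed, immediate early genes and NF-kB targets (adjusted p = 0.0402 with an estimated correlation, for both).

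The make-up of the libraries was compared as shares of counts. The 10 most abundant genes took 5.83% ± 0.159 of counts in mock and 5.80% ± 0.131 in Ca (n = 3 each, two-sided exact permutation p = 0.8). Non-coding transcripts of protein-coding genes took 1.17% ± 0.0304 and 1.13% ± 0.014 of the counts of protein-coding genes alone (exact permutation p = 0.1). Their share of TPM was likewise taken over protein-coding genes alone. For lncRNA genes the shares of all counts were 0.924% ± 0.0888 and 0.860% ± 0.0457 (exact permutation p = 0.4). With 3 libraries against 3 the smallest p this test can give is 0.1, so it cannot pass 0.05. The non-coding share of counts did not overlap between the labels, whereas the non-coding share of TPM did (0.684 to 0.703% in mock and 0.654 to 0.699% in Ca, exact permutation p = 0.5).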

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

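The tests without the libraries labelled mock 2 and Ca 2, and those without unmatched transcripts, were chosen only after the results were seen. The counts of 0 genes higher and 0 lower (306 at an unadjusted p under 0.05) were also 0 under every alternative named in the methods but 3. DESeq2's Wald test gave 35 higher and 37 lower (33 and 36 by 2-fold or more), nearly all of them unmatched transcripts, and 1 higher (1 by 2-fold or more) and 0 lower with these left out, where 9 lists were higher. Without the libraries labelled mock 2 and Ca 2 there were 1396 higher and 788 lower (428 and 196 by 2-fold or more), with 15 lists higher and 2 lower. That setting has fewer samples, chosen on the outcome. There camera ranked the list of fungal recognition genes higher, not lower (adjusted p = 0.00398), but it did not pass with an estimated correlation (adjusted p = 0.280), its median log2 fold change was -0.034 and its calls went both ways (12 higher, 9 lower), so no direction is given for it. The 8 lists higher by camera became 0 with an estimated correlation and 0 by fry, ranged from 8 to 11 under other scalings, filters and tools, and from 0 to 13 (0 to 1 lower) when 1 library was left out in turn. Scaled by library size only, the median log2 fold change was -0.031. With TPM in place of counts the Ca minus mock differences in shares were -0.607 percentage points for the 10 most abundant genes, -0.0147 for non-coding transcripts and -0.132 for lncRNA genes (exact permutation p = 0.4, 0.5 and 0.7). The same-numbered libraries did not deviate together (r = -0.076, -0.239 and -0.049), and no library deviated most like its own number, but these deviations are from the means of the labelled groups, so mock 2 and Ca 2 lying with the other group push them apart and the check cannot show whether the numbers pair the samples. The labels name no shared culture or day for a number. With the number as a replicate block, 0 genes were higher, 0 lower and 8 lists higher. The fit without mitochondrial genes was not run, as the tables list none. For genes such as Tnf the limit was the spread between libraries of 1 label (SD of 83.4 CPM in mock), not depth. In simulation the spread fitted to these labels left 28% of 2-fold changes called, against 88% at a dispersion of 0.01. The changed features were drawn at random from all those tested, whose median SE was 0.258. Tnf had a SE of 1.32, so these shares do not give the power for such genes.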

Other observations

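All tests in this part were chosen after the results were seen. Some genes, chosen after their values were seen, were least abundant in the library labelled mock 2, in Ca 1 and in Ca 3. The 20 named genes with a mean of 20 CPM or more at the negative end of the first principal component included Hpgd, which encodes an enzyme that breaks down prostaglandins, at 37.0, 5.58 and 36.0 CPM in mock 1 to 3 and 5.66, 33.3 and 5.53 CPM in Ca 1 to 3. Among them were also the nucleic acid sensor gene Tlr8 (10.2 CPM in mock 2 and 39.3 CPM in Ca 2), the iron exporter gene Slc40a1 of the metal list (11.3 and 43.1 CPM), the pro-apoptotic gene Bmf (9.01 and 38.1 CPM), the p53 target Trp53inp1 (21.9 and 105 CPM) and the translation repressor gene Pdcd4 (27.4 and 73.5 CPM). These are values per library, and no test between labelled groups passed for them.

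The 25 named genes with the largest spread over the 6 libraries included several outside the lists. Gpr84, a receptor gene for medium-chain fatty acids, stood at 6.35, 112 and 2.98 CPM in mock 1 to 3 and 118, 7.82 and 113 CPM in Ca 1 to 3. The growth factor gene Pdgfb stood at 326 CPM in mock 2 and 44.7 CPM in Ca 2, the elastase gene Mmp12 at 160 and 23.8 CPM, and the endocytic recycling gene Ehd1 at 386 and 58.9 CPM.

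The library labelled mock 2 had the profile of Ca 1 and Ca 3, and the library labelled Ca 2 that of mock 1 and mock 3. A difference in depth is argued against. Total counts of mock 2 (18226129) and Ca 2 (18747645) were alike, yet their profiles correlated at only 0.919. After thinning all libraries to the shallowest in 10 draws, the smaller margin stayed between 0.0369 and 0.0374. A margin was the lowest correlation with the other group's 2 remaining libraries minus the highest with its own group. The remaining libraries were Ca 1 and Ca 3 for mock 2, and mock 1 and mock 3 for Ca 2. The genes compared kept many counts after thinning, so alone it was a weak test. The margins, 0.0523 for mock 2 and 0.0362 for Ca 2, restate the pattern by which these 2 were picked, so they support no explanation. An exchange of the labels of 1 mock and 1 Ca library, or a numbering that alternated conditions, may be the cause and stays open. That mock 2 met a stimulus while Ca 2 did not respond stays open too, and the 2 explanations cannot be told apart. Distances of list scores were taken only over the lists that passed camera with the preset correlation. Their median from mock 2 to the nearer of Ca 1 and Ca 3 was 0.022, against 0.067 between Ca 1 and Ca 3. Taking the nearer of 2 libraries makes the first value smaller by construction. For chemokines mock 2 lay further away (0.074 against 0.033), while the other lists that passed had the smaller distance for mock 2. These distances do not place mock 2 for the lists left out. An equal exposure would also give such distances, and fungal reads were not analysed here. The labels were kept as deposited.

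With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The labelled split gave 0 called genes by edgeR (306 at an unadjusted p under 0.05, and 72 calls by DESeq2), and the highest other split gave 3846, or 743 against 0 at 2-fold or more. A count of 0 is reached by all 10 splits whatever the data, so at both thresholds this says nothing about chance. The highest split set mock 1, mock 3 and Ca 2 against the rest, and the 8 other splits gave 0. That grouping was already seen in the correlations and the first principal component, so its calls restate the same pattern from the same counts. For lists, the labelled split gave 8 calls, and 8 of the 10 splits, itself among them, gave 8 or more. The other splits ranged from 5 to 16. The 8 lists higher in Ca were thus no more than most splits of these libraries gave.

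DESeq2's 72 calls were 95.8% unmatched transcripts, which made up 24.8% of features tested. A candidate explanation is the division of reads among similar transcripts missing from the reference table, whose estimated counts can fall to 0, or round to it, in some libraries. With those transcripts left out DESeq2 called 1 gene, but taking out 69 of the 72 calls had to leave few, so this decides nothing and the explanation stays open. The splits were again too few for a share under 0.05. Of the 10, the labelled one included, 4 gave 72 or more, with 5275 in the highest other, so 72 calls did not set the labelled split apart. Named genes were called under most other splits too. Mock 1, mock 2 and Ca 2 against the rest gave 87 calls, 77 of them unmatched. Mock 1, mock 3 and Ca 3 against the rest gave 65, 56 of them unmatched. Mock 1, Ca 1 and Ca 3 against the rest gave 36, all unmatched. The 1 gene left, Tmem245, did follow the labels, with 12.4, 10.4 and 15.8 CPM in mock 1 to 3 and 45.0, 41.1 and 42.4 CPM in Ca 1 to 3, and no explanation for it was tested.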
